A study of Mus musculus with 5 samples.

How the data were processed

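Total RNA from mouse pancreas was labelled and hybridised to Affymetrix mouse gene arrays, per the labels' protocols. The deposited table holds log2 expression values, made by the authors with RMA and Partek 6.5, per the submitters' processing notes. RMA corrects the background, normalizes arrays by quantiles and summarises probes. The exact settings and the genome build are not given in the sources used here, so no coordinates are printed. The deposited log2 values were used as they stand, and fold changes are powers of 2 of differences of means.

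Samples were grouped by the genotype in their titles and in the genotype tag, which match the stated design: 2 Nupr1-null and 3 Nupr1 wild-type arrays, all with Kras-G12D. Other label text conflicts with this. The descriptions of the wild-type samples speak of a homozygous deletion of exon 2, and the growth text calls the -/- mice wild-type. Titles number the arrays of a group as repeats, and nothing ties each array to a separate mouse, so p-values measure only the spread between these arrays. The number of arrays limits the precision.

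Probe sets were named from the platform annotation in GEO. Of 35557 rows, 21789 had 1 gene symbol, 1621 had several and 12147 had none. Probe sets with several symbols name no gene here, which leaves out Kras, Cdkn1a, Trp53, amylases and haemoglobins among others. Through Entrez numbers in a gene table of the mouse reference 0 symbols needed an update. For each gene the probe set with the highest mean was kept, giving 19938 genes, 999 of which had more than 1 probe set. Of the 13768 rows with no or several symbols, 941 had an unadjusted p below 0.05, and 0 of all 35557 rows had an adjusted p below 0.05. All 5 value columns belong to a sample.

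The tests were chosen before the data were examined. Null and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariates) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All limma tests were two-sided. A second count took genes with an unadjusted p below 0.05 and a difference of at least 1 on the log2 scale. Gene lists, 32 in number with 877 entries of which 797 matched a tested gene, were tested with camera at a preset correlation of 0.01, again with the correlation estimated for each list, and with fry. Benjamini-Hochberg adjustment ran over the 32 lists. The lists covered pancreatic cell types, lesion and senescence programmes, DNA methylation and chromatin genes, stress and metabolism, immune cells, and tissues that a dissected pancreas may carry. Median, mean and test differed in sign for the senescence inhibitor, ER stress, adipocyte and intestinal lists, all with medians near 0.

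Genes were named by a rule fixed in advance: Nupr1, Kras and Dnmt1; the 10 largest differences in each direction among genes past the adjusted threshold whose groups do not overlap, filled up, since none passed, from genes with an unadjusted p below 0.05 and groups that do not overlap; and the 3 members with the smallest p of each list described by its members. Predicted models, RIKEN clones and olfactory or vomeronasal receptors were not named under the second part. Other named genes are said to have been chosen after their values were seen, or belong to the lymph node genes tested in the closing part.

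Many values repeat between arrays. Between 18.8% and 26.9% of genes had identical values on a pair of arrays, 12906 genes (64.7%) had at least 2 identical values, and 1090 had identical values within both groups and so no residual spread. The step that made these repeats is not given in the sources used here. They leave limma with 0.66 prior degrees of freedom beside 3 residual ones, so variances were moderated little. No pair of arrays was a copy, and the closest pair, wild-type replicates 2 and 3, correlated at 0.995 over genes.

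The pipeline was tested on simulated data with 19938 genes in the same design, each gene with its residual spread from the real fit. The 1090 genes without residual spread had none in the simulation either, so a change set in one of them is easily recovered. Changes of 1 on the log2 scale were recovered at the adjusted threshold in 60% of 100 genes and changes of 2 in 83%, with 9 unchanged genes called. A shifted list was called and 0 others were, but genes were drawn independently, so lists of correlated genes were not tested. Alternatives covered repeated quantile normalization, median centring, a filter on dim genes, other probe rules, other variance moderation, array weights, the replicate number as a block, leaving out each array, and the arrays that share a sample code. Those added after the data were seen used lymphoid transcripts or Xist as a covariate, left out both lymphoid-rich arrays, or kept the 7032 genes with 5 different values. The lymphoid covariate was the mean of the B and T cell list genes, so it takes up much of those lists' own differences by construction. Wild-type replicate 3 alone has the number 3, so the block gives the same differences as leaving that array out. The arrays that share a sample code are those left without null replicate 1. Counts of alternatives include both settings of each such pair. Gene order for the neighbours of Nupr1 came from the assembly GRCm38.p6, used for order only. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.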

Results

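Gene expression was measured in the pancreas of 5-week-old C57BL/6 mice carrying oncogenic Kras-G12D, an activated Ras allele that drives early precancerous change in this organ. Nupr1, the gene under study, encodes a small chromatin-associated protein that pancreatic cells induce under stress. The samples formed 2 groups, Nupr1-null (Nupr1 -/-, 2 arrays) and Nupr1 wild-type (Nupr1 +/+, 3 arrays). For each Affymetrix mouse whole-transcript array 200 ng of total RNA was the input. Values were deposited as log2 RMA expression for 35557 probe sets, with array medians over all probe sets between 7.06 and 7.13, and 19938 genes could be tested by name. The study title asks how a genetic signal is passed on to the epigenome during Kras-induced senescence and the formation of pancreatic intraepithelial neoplasia (PanIN), the early lesions of the duct-like epithelium. The comparison implied by the design is Nupr1-null against Nupr1 wild-type pancreas, and every difference below is null minus wild-type on the log2 scale.

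Nupr1 itself was lower in the null pancreas but still among the brightest transcripts. It measured 12.53 and 12.60 in the null arrays and 12.97, 13.61 and 13.40 in the wild-type arrays, that is 12.57 ± 0.054 (SD, n = 2) against 13.33 ± 0.33 (SD, n = 3). The difference of -0.76 (SE 0.22), or 1.70-fold lower, did not pass adjustment over all genes (limma, adjusted p = 0.685). Nupr1 lay between the 99.5th and the 99.8th percentile of all genes on every array. Where its probes lie relative to the deleted part of the gene is not known here, so this level is a limited check of the genotype labels. It ran in the labelled direction on all 5 arrays. Dnmt1, the maintenance DNA methyltransferase, differed by -0.35 (SE 0.11, adjusted p = 0.685), at 7.74 on both null arrays and at 7.91, 8.13 and 8.22 on the wild-type arrays. Kras had no probe set that named it alone and was not measured.

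Among genes with an unadjusted p below 0.05 and groups that do not overlap, a limit that most of the 150 genes with a difference of at least 1 did not meet, the largest higher values in null pancreas included a group of tissue kallikreins, secreted serine proteases, and a pair of glycerophosphodiester phosphodiesterases. Klk1b11 lay 1.53 higher (SE 0.065; 2.88-fold; adjusted p = 0.332) and Gdpd3 1.49 higher (SE 0.082; 2.80-fold; adjusted p = 0.332). Klk1b7-ps, Klk1b24 and Klk1b8 lay higher by 1.06, 1.00 and 0.90. These kallikrein genes are close copies of each other, so probes may not separate them. Gde1, the second phosphodiesterase, lay 1.04 higher, the membrane glycoprotein gene Prom2 1.04, Vsig2 0.93, the tyrosine-breakdown enzyme gene Fah 0.90 and the zinc transporter gene Slc30a2 0.84. Fah was also a member of the liver list, and null replicate 1 carried liver transcripts. The differences of Klk1b24 and Vsig2 leaned on null replicate 1 too, at 9.61 and 10.04 there against 8.86 and 9.32 on null replicate 2. In the other direction, Ppy, which encodes pancreatic polypeptide, measured 9.05 ± 0.28 (SD, n = 2) in null and 11.22 ± 0.33 (SD, n = 3) in wild-type pancreas, a difference of -2.17 (SE 0.26) or 4.49-fold lower. Tmc5, a transmembrane channel-like gene, differed by -1.96, the Rac-inactivating gene Chn2 by -1.19, the macrophage-associated gene Retnla by -1.17, and D17H6S56E-5 by -1.10. The differences of Gde1 and Retnla leaned on wild-type replicates 2 and 3, which carried lymphoid transcripts. Gde1 measured 8.19 and 8.10 there against 9.02 on wild-type replicate 1, and Retnla 9.45 and 9.27 against 8.48. The proliferation marker Mki67 differed by -1.03, glucagon (Gcg) by -0.88, the mitotic kinesin Kif11 by -0.82 and cyclin A2 (Ccna2) by -0.75. Each of these genes had both null values on the same side of all 3 wild-type values, and none passed the adjusted threshold.

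**Figure D1:**
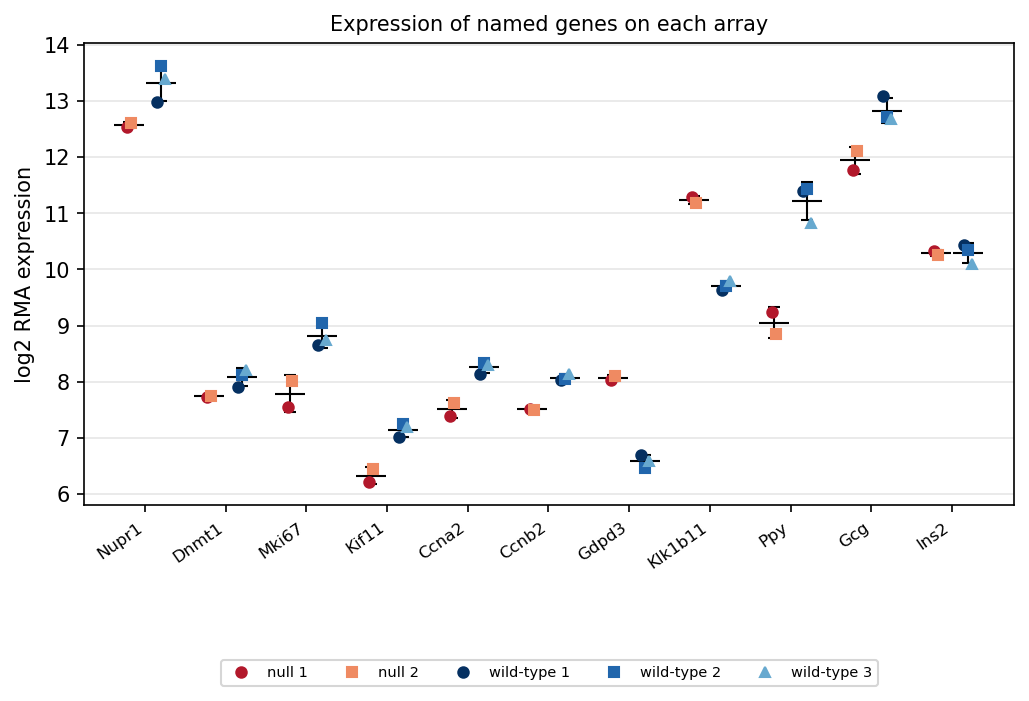
Log2 RMA expression (vertical axis) of 11 genes on each of the 5 arrays, with symbols for single arrays and horizontal bars with whiskers for the group mean and SD (n = 2 null, n = 3 wild-type). Klk1b11 and Gdpd3 lay 1.53 and 1.49 higher in the null arrays and Ppy differed by -2.17, while the insulin gene Ins2 lay at 10.29 in null and 10.30 in wild-type pancreas.

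Across all genes, limma with Benjamini-Hochberg adjustment called 0 of 19938 genes, the smallest adjusted p being 0.332, and 3 genes without moderation of the variance. Those were Bhlhb9 at -0.16, Cradd at 0.015 and A730018C14Rik at 0.14, which had identical values in all 3 wild-type arrays and were named after their values were seen. At an unadjusted p below 0.05 there were 934 genes, 627 higher and 307 lower in null, 5% of all genes being 997. With each array centred on its median that split was 810 higher and 217 lower, and over all 35557 rows it was 1021 higher and 922 lower. The majority turned without null replicate 2 (1577 higher, 2215 lower), without wild-type replicate 1 (979 and 1072), with lymphoid transcripts as a covariate (1005 and 1354) and without both lymphoid-rich arrays, wild-type replicates 2 and 3 (1172 and 1584). A difference of at least 1 on the log2 scale together with that unadjusted level was met by 12 genes, 6 in each direction, and by 262 when wild-type replicate 1 was left out, 68 without null replicate 2, 5 without null replicate 1 and 7 without wild-type replicate 3. The groups did not overlap for 13.4% of genes, a share that ties between arrays lower, and for 1901 of the 7032 genes with 5 different values, where unrelated genes would give 20%. Genes vary together, so this share is not a test.

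Genes of cell division lay lower in null pancreas across nearly the whole list. Of 48 measured E2F target and proliferation genes, 46 lay lower in null pancreas, 17 of them at an unadjusted p below 0.05 and 0 higher at that level, and 30 had both null arrays below all wild-type arrays. The median difference was -0.25. Ccnb2, a B-type cyclin, lay at 7.52 and 7.50 in null and at 8.03, 8.06 and 8.14 in wild-type pancreas, a difference of -0.56 (SE 0.040, adjusted p = 0.332). The spindle assembly gene Tpx2 differed by -0.36 and Kif11 by -0.82. Adjusted over the list alone, 6 members passed, and 0 over all genes. The list as a whole lay lower than other genes in camera with a preset correlation (adjusted p = 1.49e-19) and was called on leaving out each array in turn, but it was not called with an estimated correlation (adjusted p = 0.719). The 5 arrays can be split into 2 and 3 in 9 other ways, and in 5 of these camera with the preset correlation also gave this list an unadjusted p below 0.05. The smallest was 1.77e-14, for wild-type replicates 1 and 2 against the rest, beside 4.65e-21 in the real split. That other split keeps both null arrays together, so it shares part of the genotype difference. Among splits that part the null arrays, the smallest camera p was 0.0003, for null replicate 1 with wild-type replicate 3. A camera p below 0.05, though not one as small as 4.65e-21, thus also arose in splits that part the null arrays. The list's median was -0.32 when wild-type replicates 2 and 3, which carried lymphoid transcripts (the lymphoid-rich arrays), were both left out, a setting with 1 wild-type array against 2 null arrays.

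Of 22 DNA methylation genes 13 lay lower in null pancreas and 9 higher, with a median of -0.035 and a camera adjusted p of 0.0214 (adjusted p = 0.719 with an estimated correlation). The members at the front were Uhrf1, which brings Dnmt1 to newly copied DNA, at -0.35, Dnmt1 at -0.35 and the methyl-binding gene Mbd2 at -0.079. Adjusted over the list alone, 0 members passed. The call was lost without null replicate 1 (median -0.019), null replicate 2 (-0.055) or wild-type replicate 2 (-0.015), and without both lymphoid-rich arrays the median was -0.0062. Histone-modifying enzymes had a median of -0.049 over 36 genes, 22 of them lower (camera adjusted p = 0.0482, and adjusted p = 0.719 with an estimated correlation), with Hdac5 at 0.12, Hdac3 at 0.16 and Suz12 at -0.13. That call was lost without null replicate 2 (median -0.037), wild-type replicate 2 (-0.029) or wild-type replicate 3 (-0.033).

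The 28 measured digestive enzyme genes of the acinar cells had a median difference of 0.011, with 18 higher and 10 lower, and were not called (camera adjusted p = 0.0972), but they were called higher without null replicate 2 (median 0.019, adjusted p = 0.0162) or wild-type replicate 1 (0.013, adjusted p = 0.0386). Of the 28, 21 had means within 1 log2 unit, a distance chosen after the values were seen, of the lowest array maximum (maxima 14.60 to 14.69), where the scale can compress differences, so no stability is read from them. The other 7 had a median of 0.088, with 5 higher. The phospholipase Pla2g1b lay 0.092 higher, the trypsinogen Try10 0.071 and the trypsin inhibitor Spink1 0.20. Genes of acinar identity and secretion lay higher, 14 of 18, with a median of 0.14 (camera adjusted p = 0.00546, and adjusted p = 0.727 with an estimated correlation). Among them Xbp1, a transcription factor of secretory cells, lay 0.20 higher, the vesicle cargo gene Tmed6 0.37 and the water channel gene Aqp8 0.75. The call was lost with quantile normalization repeated (median 0.060, adjusted p = 0.221), with lymphoid transcripts as a covariate (0.083), without null replicate 1, which carried liver transcripts (0.082), and without both lymphoid-rich arrays (0.047). Metaplasia and PanIN markers had a median of -0.076, with 22 of 30 lower (camera adjusted p = 0.0103, and adjusted p = 0.727 with an estimated correlation). The gastric genes Gkn3 and Gkn1 differed by -0.58 and -0.19 and clusterin (Clu) by 0.26, and the list's median was 0.0052 without both lymphoid-rich arrays. Without null replicate 2 it was -0.13 and the list was not called.

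Of 21 islet hormone and granule genes 16 lay lower in null pancreas, with a median of -0.069 (camera adjusted p = 0.0337, and adjusted p = 0.766 with an estimated correlation). Ppy, Gcg and peptide YY (Pyy) led the list, at -2.17, -0.88 and -0.58, and Ppy alone passed when adjusted over the list alone. Ins2 differed by -0.00047 and somatostatin (Sst) by -0.16, both named here after their values were seen. The list's median turned to 0.070 without wild-type replicate 1, and the call was also lost without null replicate 2, at -0.018. It was 0.0062 with the level of Xist as a covariate, and -0.38 without both lymphoid-rich arrays, where the 1 wild-type array left, replicate 1, had a mean of 9.24 for this list against 8.59 to 8.83 on the others. Xist, the RNA of the silenced X chromosome, measured 12.12 and 12.08 in wild-type replicates 1 and 3 and between 6.01 and 6.98 on the other arrays. The Y-linked gene Uty ran the other way. By these transcripts both null arrays and wild-type replicate 2 were male, and wild-type replicates 1 and 3 female. Sex is therefore partly confounded with genotype in every gene and list difference given here.

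Immune genes lay lower in the null group, but the difference followed 2 wild-type arrays. The B and plasma cell list had a median of -0.997 over 22 genes, 20 of them lower (camera adjusted p = 0.000134), the T and NK cell list -0.54 over 26 genes, all 26 lower (4.34e-06), and the interferon list -0.57 over 26 genes, all 26 lower (3.67e-06). With an estimated correlation each had an adjusted p = 0.727. Macrophage and dendritic cell markers had a median of -0.28, with 24 of 28 lower (camera adjusted p = 0.00152, and adjusted p = 0.727 with an estimated correlation). Named members were Blk at -0.48, Cd22 at -1.14 and Sdc1 at 0.18 for B cells, Cd6 at -0.40, Bcl11b at -0.21 and Cd8b1 at -0.92 for T cells, Mx1 at -1.18, Oas3 at -0.39 and Ifit1 at -1.29 for interferon, and Fcgr1 at -0.068, Itgax at -0.41 and H2-Eb1 at -1.34 for macrophages. The mean of the B and T cell lists was 7.68 and 8.11 in wild-type replicates 2 and 3, and 6.63, 6.73 and 6.53 in null replicates 1 and 2 and wild-type replicate 1. Without those 2 arrays the medians of these lists were 0.23 for B cells, 0.078 for T cells, 0.13 for interferon and 0.46 for macrophages. The B cell call was lost without null replicate 2 (median -1.04). The macrophage call was lost without null replicate 2 (-0.23), wild-type replicate 2 (-0.18) or wild-type replicate 3 (-0.096).

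**Figure D2:**
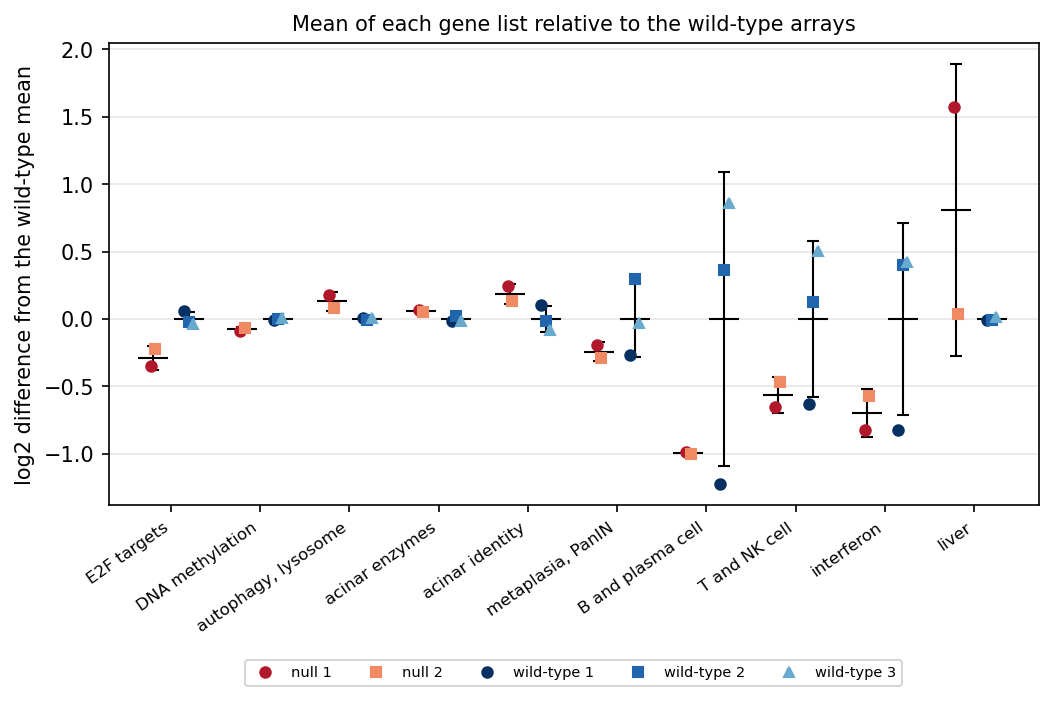
Mean log2 expression of the genes of 10 lists on each array, as the difference from the mean of the 3 wild-type arrays (vertical axis, log2), with symbols for single arrays and bars with whiskers for the group mean and SD (n = 2 null, n = 3 wild-type). Both null arrays lie below the wild-type arrays for E2F targets, the immune lists are set by wild-type replicates 2 and 3, and the liver list is raised in null replicate 1 alone.

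Genes of autophagy and the lysosome lay higher in null pancreas, 23 of 26, with a median of 0.11 (camera adjusted p = 6.46e-05, and adjusted p = 0.719 with an estimated correlation). The autophagosome genes Gabarapl1 and Map1lc3a lay 0.31 (SE 0.037) and 0.48 (SE 0.083) higher and the lysosomal membrane gene Lamp1 0.058, and Gabarapl1 alone passed when adjusted over the list alone. The call was lost without null replicate 1, at a median of 0.047. Nuclear-encoded oxidative phosphorylation genes lay higher in 30 of 33 cases, with a median of 0.16 (camera adjusted p = 4.21e-05, and adjusted p = 0.727 with an estimated correlation). Atp5d lay 0.25 higher, Uqcrc1 0.32 and Ndufb5 0.23, and the median was -0.011 without both lymphoid-rich arrays. That call was also lost without null replicate 1, at a median of 0.14. Cytosolic ribosomal protein genes had a median of 0.044, with 23 of 28 higher (camera adjusted p = 0.0214, and adjusted p = 0.727 with an estimated correlation), and -0.019 after quantile normalization was repeated. Rps14 lay 0.15 higher, Rps18 0.12 and Rpl22 0.12, and the call was lost without null replicate 1 (median 0.027), null replicate 2 (0.025) or wild-type replicate 1 (0.030). The liver list had a median of 0.82, with 14 of 16 higher (camera adjusted p = 0.00108, and adjusted p = 0.727 with an estimated correlation), and 0.031 without null replicate 1. Besides Fah, its leading members were Hpx at 0.62 and Serpina1d at 0.35. Albumin (Alb), looked up after the values were seen, measured 11.89 there and between 7.17 and 7.65 on the other arrays.

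Lists of senescence and of Ras output, processes tied to the study title, had medians near 0. Cell cycle inhibitors and senescence genes had a median of -0.0043, with 11 higher and 13 lower of 24 (camera adjusted p = 0.466), among them the pocket-protein gene Rbl1 at -0.28, Cdkn2d at -0.064 and Lmnb1 at -0.16. The secretory factors of senescent cells had a median of -0.033, with 24 of 37 lower (adjusted p = 0.123). They were called lower in 5 of 20 alternatives, among them without wild-type replicate 1 (median -0.063, adjusted p = 0.000897), and higher in 1. Members were Plau at 0.33, Igfbp3 at -0.45 and Il6 at 0.071. The list around Foxo3, Skp2, p27 and Rb had a median of -0.030 (adjusted p = 0.789), with Ccne1 at -0.30, Skp2 at -0.16 and Akt1 at 0.23. Ras and MAPK output genes had a median of -0.062, with 19 of 24 lower (camera adjusted p = 0.0273, and adjusted p = 0.727 with an estimated correlation). Etv5 lay at -0.71, Phlda1 at -0.19 and Fosl1 at -0.050, and the call was lost without null replicate 1 (median -0.025) or wild-type replicate 2 (-0.063).

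In all, camera with a preset correlation called 15 of 32 lists, 10 lower and 5 higher in null pancreas, and 0 with an estimated correlation. The self-contained test fry called 0 for a shared direction and 1, the E2F list, for change in either direction (adjusted p = 0.00755). Of the 15 called lists, 3 were called on leaving out each array in turn, namely E2F targets, T and NK cells and interferon. For T and NK cells and interferon each such fit kept wild-type replicate 2 or 3, the lymphoid-rich arrays, so it could not test their part. Without both, the medians of these lists were 0.078 and 0.13. Splitting the same 5 arrays into 2 and 3 in the 9 other ways gave between 8 and 16 called lists.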

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

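Nupr1 was lower in null pancreas under all 19 alternatives, by between -0.41 and -1.12 on the log2 scale, with adjusted p from 0.273 to 0.789. Of 108 other named genes 106 kept their direction. The exceptions were Camp, at 0.0046 with quantile normalization repeated and 0.0012 with centred arrays, and Uty, at -0.43 with Xist as a covariate. Kept signs test little. Where groups do not overlap, as for Nupr1, leaving out arrays cannot turn a sign, and moderation or filters change no difference. Alternatives using Xist, lymphoid transcripts or 5 different values, or without both lymphoid-rich arrays, were chosen after seeing the data. Causes of reversals were not tested.

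The count of genes past the adjusted threshold was 0 in most alternatives. It was 3 with no moderation of the variance, and between 0 and 1710 on leaving out each array in turn. Leaving out null replicate 1, which also leaves only the arrays with a T23 code, gave 1154 genes, 836 of them with no residual spread, and leaving out null replicate 2 gave 1710, 1031 of them without spread. The lone null array is then assumed to vary like the wild-type arrays. With only genes of 5 different values the count was 0 and the smallest adjusted p 0.0945. The 12 genes with a difference of at least 1 became 53 at 1.5 times, 44 over every row of the table, 5 with a T23 code only, 35 with Xist as a covariate and 19 without both lymphoid-rich arrays. They ranged from 5 to 262 on leaving out each array. The 15 called lists became 0 with an estimated correlation, 0 with fry, 9 with a T23 code only and 8 with lymphoid transcripts as a covariate, and ranged from 9 to 16 on leaving out each array.

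With the replicate number as a block, limma called 0 genes, 8 genes had a large difference, Nupr1 differed by -0.73 and 14 lists were called. No label ties same-numbered arrays to each other. Their deviations from the group means correlated at 0.070 and 0.076 over genes. The deviations of the 2 null arrays are exact opposites, so these correlations can neither show nor exclude a pairing. List medians that turned under the block were 0.013 for the Foxo3 list and 0.096 for adipocytes.

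List medians that turned sign were mostly close to 0. With quantile normalization repeated they were 0.018 for adipocytes, -0.019 for ribosomal proteins, 0.0046 for neutrophils, 0.013 for senescence inhibitors and -0.0024 for sex-linked genes. With centred arrays they were 0.0021 for the Foxo3 list, 0.017 for adipocytes, 0.0051 for ER stress, 0.0039 for endothelium, 0.026 for neutrophils and 0.027 for senescence inhibitors. Array weights gave 0.037 for ER stress, -0.0093 for immediate-early genes and 0.015 for islets. Genes above the median level gave -0.22 for sex-linked genes. Genes with 5 different values gave 0.068 for the Foxo3 list and -0.048 for immediate-early genes.

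With Xist as a covariate the medians were -0.036 for NUPR1-related genes, 0.077 for adipocytes, -0.059 for ducts, 0.014 for ER stress, -0.019 for immediate-early genes and 0.0062 for islets. With lymphoid transcripts as a covariate they were 0.064 for the Foxo3 list, 0.081 for adipocytes, -0.0020 for ducts, 0.0093 for endothelium, 0.27 for macrophages, 0.019 for senescence inhibitors, 0.022 for secretory factors, -0.030 for sex-linked genes and 0.14 for stellate cells. Without both lymphoid-rich arrays they were 0.23 for B cells, 0.072 for the Foxo3 list, 0.078 for T cells, 0.078 for adipocytes, 0.038 for endothelium and 0.13 for interferon. In that setting macrophages gave 0.46, metaplasia 0.0052, oxidative phosphorylation -0.011, senescence inhibitors 0.018, secretory factors 0.022, sex-linked genes -0.026 and stellate cells 0.19. With a T23 code only they were -0.0042 for pancreatitis, 0.096 for endothelium, 0.0089 for senescence inhibitors and 0.0022 for stellate cells.

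Of 63 list values that turned sign, 13, from 7 lists, were also called by camera in the turned direction. Without both lymphoid-rich arrays, macrophages, stellate cells, B cells, adipocytes and secretory factors were called higher in null. That setting leaves 1 wild-type array against 2 null arrays, with 1 residual degree of freedom from the null arrays alone, so its calls do not separate genotype from what is particular to wild-type replicate 1. With lymphoid transcripts as a covariate, adipocytes (0.00942), stellate cells (0.00957) and macrophages (0.0289) were called higher, and with Xist as a covariate ducts were called lower (0.00418). Adipocytes were called higher under the block (0.0112) and without wild-type replicate 3 (0.00391), and endothelium without null replicate 1, the T23 setting with 1 null array (0.00516).

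Of the 90 calls lost without a turn in the sign of the median, 30 were lost with an estimated correlation or fry, 28 on leaving out an array in turn or with a T23 code only, and 32 elsewhere. Of the 32, lymphoid transcripts as a covariate lost 10 and leaving out both lymphoid-rich arrays 5. Genes above the median level and every row lost 3 each. Repeated quantile normalization lost 2, acinar identity (median 0.060) and Ras output (-0.070), and the block, Xist and 5 different values lost 2 each. The mean of all probes, trend and robust moderation, and array weights lost 1 each.

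The 23 calls that a list gained without turning sign were these. Stellate cells gained one lower with quantile normalization repeated (median -0.079), centred arrays (-0.0032), array weights (-0.23), without wild-type replicate 1 (-0.18), with Xist (-0.34) and with 5 different values (-0.12). Secretory factors gained one lower with centred arrays (-0.0017), array weights (-0.058), without wild-type replicate 1 (-0.063), with Xist (-0.064) and with 5 different values (-0.12). Digestive enzymes (0.019), pancreatitis (0.20, higher) and endothelium (-0.15, lower) gained one without null replicate 2, which leaves 1 null array, and digestive enzymes without wild-type replicate 1 (0.013). Genes near Nupr1 gained one lower with quantile normalization repeated (-0.029) and with 5 different values (-0.47), NUPR1-related genes one higher without wild-type replicate 2 (0.12), and neutrophils one lower with Xist (-0.015). ER stress gained one lower with lymphoid transcripts as a covariate (-0.17). Without both lymphoid-rich arrays, ER stress (-0.19), pancreatitis (0.20) and immediate-early genes (0.018) gained one.

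On leaving out each array in turn, medians ranged from -0.18 to 0.017 for stellate cells, -0.026 to 0.0089 for senescence inhibitors, -0.0042 to 0.20 for pancreatitis and -0.15 to 0.096 for endothelium. They ranged from -0.093 to 0.096 for adipocytes, -0.20 to 0.070 for islets, -0.10 to 0.13 for ER stress, -0.015 to 0.022 for immediate-early genes and -0.042 to 0.013 for the Foxo3 list. Of the list values under alternatives whose median did not turn sign, 462 kept their side of the threshold, 90 lost a call and 23 gained one. The E2F list was called in 18 of 20 alternatives, with medians from -0.32 to -0.16. No measure of signal over background per probe was used here, so the lowest level that could be told from background is unknown.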

Other observations

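The tests of lymph node genes and of the 99 genes within 50 places of Nupr1, Gdpd3 left out, were fixed before their results were seen, and all other tests of explanations in this part were chosen afterwards. Klk1b22, Glycam1, Ms4a1, Cxcl13, Dbp, Arntl, Nr1d1, Nr1d2, Serpina1c, Ahsg, Mt1 and Mt2 were named in this part after their values were seen. Stress and support lists outside the main description were not called by camera with all arrays, and its adjusted p is given for each. Of 20 alternatives, 2 called the pancreatitis list higher, 2 the endoplasmic reticulum stress list lower, 1 the NUPR1-related list higher, 1 the immediate-early list higher and 1 the ductal list lower. Genes tied to NUPR1 and stress survival, Nupr1 included, had a median of 0.11 over 18 genes (0.333), or 0.031 to 0.17 on leaving out each array in turn. Endoplasmic reticulum stress genes had a median of -0.026 (0.885), and the acute pancreatitis and regeneration list one of 0.11 (0.278), with Clu at 0.26, Saa1 at 0.31 and Reg3d at 0.24. Immediate-early genes had a median of 0.0062 (0.885). Ductal markers had a median of 0.069 (0.466), with Muc1 at 0.35, Sox9 at 0.26 and Ambp at 0.28.

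Lists of other cell types were not called with all arrays. Medians were -0.035 for stellate cells and matrix (0.163), -0.0057 for neutrophils and mast cells (0.311), -0.028 for endothelium and pericytes (0.466), -0.015 for adipocytes (0.685), 0.099 for blood genes (0.316) and 0 to 2 decimals for intestinal markers (0.789), with the camera adjusted p in brackets. The stellate list was called in 8 of 20 alternatives, 6 lower and 2 higher in null, with medians from -0.34 (Xist as a covariate) to 0.19 (without both lymphoid-rich arrays). Endothelium was called in 3 of 20 and adipocytes in 4 of 20. Genes listed in advance as lying near Nupr1 had a median of -0.042 (0.0972) and were called lower in 2 of 20 alternatives, with medians of -0.029 with quantile normalization repeated and -0.47 over the 5 of 21 members with 5 different values. Sex-linked transcripts had a median of 0.025 (0.708). The kallikrein family Klk1b had 10 measured members, of which 9 lay higher in null, 8 of them with groups apart, and 7 members had an unadjusted p below 0.05. The exception, Klk1b22, measured 8.08 and 7.96 in wild-type replicates 1 and 3 and between 6.72 and 6.88 elsewhere, the split that Xist shows.

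Wild-type replicates 2 and 3 carried lymphoid and interferon transcripts, with Glycam1, a mucin of lymph node vessels, at 9.21 and 11.54 against 5.73 to 5.86 on the other arrays, and Ms4a1 (CD20) at 9.13 and 9.44 against 5.42 to 6.37. An effect of Nupr1 genotype as the whole cause is argued against by wild-type replicate 1, whose B and T list genes lay at a median of -0.13 relative to the null arrays, with 11 of 48 higher. Sex is argued against by Xist, which differed by 5.10 between the 2 lymphoid-rich arrays. Lymphoid tissue, such as a pancreatic lymph node, in the dissected samples is a candidate source. Of 6 lymph node genes fixed in advance, 5 lay higher in both arrays than in each of the others, with a median difference of 1.497 (range 0.17 to 2.97). Cxcl13 was brightest at 10.02 and 10.84 (5.89 to 9.31 elsewhere). Lymphocytes themselves express Ltb and Cr2, which alone was in another list, so these genes partly restate the B and T cell lists. Without them the differences were mixed, at 2.97 for Cxcl13, 1.77 for Ccl19, 0.50 for Madcam1 and 0.17 for Chst4, the exception. Inflammation with lymphoid follicles in those pancreases was not tested and stays open. The metaplasia and PanIN list was also higher on the 2 lymphoid-rich arrays, with means of 8.23 and 7.91 against 7.64 to 7.74 elsewhere. Lymphoid tissue in the dissection is thus not told apart from a difference within those pancreases.

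E2F targets and proliferation genes lay lower in both null arrays, and 5 of the 48 genes also belong to another list. As the whole cause on its own, lymphoid tissue is argued against by wild-type replicate 1, relative to which the null arrays lay at a median of -0.32 with 46 genes lower, sex by wild-type replicate 2, with a median of -0.18 and 44 lower, and liver RNA by null replicate 2 alone, with -0.16 and 44 lower. With 10 splits of the 5 arrays a share under 0.05 cannot be reached. The real split, the 1 split with so large a median, gave 0.25 in size and the highest other split 0.21. That other split sets the female arrays, wild-type replicates 1 and 3, against the male arrays, with both null arrays on the same side. Sex and lymphoid tissue together stay open beside a lower rate of cell division in Nupr1-null pancreas, since no wild-type array matches the null arrays in both; against wild-type replicate 3, which differs in both, the median was -0.19 with 42 lower, short of the -0.50 that the differences from replicates 1 and 2 add up to, though the effects need not add. For the count of 12 genes with a difference of at least 1, chance is not excluded, since 4 of the 10 splits gave as many; the highest other gave 293 and parts wild-type replicates 2 and 3 from the rest, which points to the lymphoid structure of the samples.

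Gdpd3, Gde1 and Tmc5, all among the 12 genes with a large difference, lie near Nupr1 in gene order: 5 measured genes separate Gdpd3 from Nupr1, and Gde1 and Tmc5 are direct neighbours of each other, 87 and 88 places away, yet the null minus wild-type difference was 1.04 for Gde1 and -1.96 for Tmc5. Lymphoid or liver RNA is argued against for Gdpd3 by null replicate 2 and wild-type replicate 1, which carry neither and differed by 1.42. That test was not made for Gde1, at 9.54 and 9.02 on those 2 arrays, or for Tmc5, at 6.55 and 8.09. A candidate explanation is a chromosome segment carried along with the targeted Nupr1 allele from another strain, which stays open: with Gdpd3 left out, 7.07% of the 99 genes within 50 places had an unadjusted p below 0.05 against 4.66% of other genes (Fisher's exact test, two-sided p = 0.232), 6.12% within 25 places (p = 0.499) and 8.04% of 199 within 100 places (p = 0.0398, or 7.11% and p = 0.122 without Gde1 and Tmc5). That 18.2% of the 11 large-difference genes other than Gdpd3 lay within 100 places restates Gde1 and Tmc5, which prompted that test and without which 0 of 9 did (highest other split 2.39%, 7 of 293 genes), so it lends no support; of those 9, 4 lie further away on the same chromosome, which holds 8.70% of tested genes: Mki67 139 places away and the clustered, similar kallikreins Klk1b11, Klk1b24 and Klk1b7-ps 828 to 836. An effect of Nupr1 loss on these genes was not tested against it.

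Among clock genes, Dbp at 10.64 against 8.12 to 8.64 and Arntl at 6.61 against 8.09 to 8.47 on the other arrays stood out on null replicate 1. Nr1d1 measured 11.14 and 10.71 in null and 9.94 to 10.35 in wild-type pancreas, and Nr1d2 10.66 and 9.91 against 9.49 to 9.85. Liver transcripts stood out on the same array, with Serpina1c at 9.06 against 4.01 to 4.60 and Ahsg at 9.41 against 6.52 to 6.62. The metallothioneins Mt1 and Mt2 measured 10.77 and 10.18 in wild-type replicate 1 and between 12.51 and 13.65 elsewhere. The Y-linked gene Uty measured 4.55 and 4.68 in wild-type replicates 1 and 3 and between 7.96 and 8.14 on the other arrays.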
